A study of Mus musculus with 2 samples.

How the data were processed

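Total RNA of mouse PS10 XEN cells was sequenced after transfection, with a lipid reagent, of an LNA directed against Gata6-AS or of a control LNA; per the labels' protocols the RNA was isolated with TRIzol and a column kit and made into libraries with an Illumina kit. The samples form 2 groups by their titles, control LNA and Gata6-AS LNA, with 1 library each. The titles call the reagents siRNA, while the treatment protocol calls them locked nucleic acid, which is the term used here. Gata6-AS was identified in the table through a RefSeq gene table of assembly GRCm38.p6, used for names only, in which 1010001N08Rik is a synonym of the antisense gene.

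The authors' deposited expression table gives RPKM (reads per kilobase of gene length per 1000000 reads), per the file headers, for 26127 genes with their coordinates. TopHat and the mm9 assembly are named in the submitters' processing notes, and coordinates are printed as the table gives them. The counting tool, the gene annotation, the use of strand, the treatment of duplicate and multiply mapped reads, and the version of the aligner are not given in the sources used here. A second table deposited by the authors holds log2 values of both libraries, their log2 difference and a p-value for 2099 genes, selected by the authors at a p below a limit; the largest p in it is 0.07499. These log2 differences are not log2 ratios of the RPKM values. They lay below them by a median of -0.14 for genes with a mean log2 value of the authors below 0 and above them by 0.01 above a mean of 6. They were thus computed in some other way, which is not described in the sources used here. Rows of the tables were joined by chromosome, start, end and strand, which matched 2099 rows.

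Depth was read from the RPKM values. For genes with a single exon, RPKM multiplied by length is a whole number of reads times a constant, and this constant was found from 790 genes in the control and 839 in the depleted library with a span under 3000 bp. It corresponds to 1.04e+08 reads in the control library and 1.23e+08 in the depleted library. For each named gene, the smallest whole numbers of reads that give both RPKM values at one transcript length (up to 30000 bp, within a relative tolerance of 3e-07 plus 0.0002 reads) were taken as the least number of reads behind it. The exact (Clopper-Pearson) 95% interval of the ratio of both libraries was computed from these numbers, so it is as wide as or wider than the true counts would give. It covers counting error only, since reads amplified by PCR are not independent molecules. For Lama3, near 0 RPKM in both libraries, no such whole numbers of reads were found. The floor of a library at a value of 0 is 3 reads.

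With 1 library per group no test between conditions is possible, and none was made. The measure is the difference of log2(RPKM + 1), depleted minus control, on the values as deposited. Genes needed a mean of at least 1 RPKM over both libraries, and 10 small RNA features were left out because short features have unstable RPKM. Exact duplicate rows count once; 59 symbols stand on more than 1 row, and lists use the row with the highest mean. A gene passed the size rule at a difference of at least 1 in either direction. For each of 29 gene lists, the median difference of its measured members was placed among those of 10000 random lists of the same size, matched on mean expression in 10 equal bins. A list needed 5 members, which left 26, and stood apart in the top or bottom 2.5%. The percentile describes these libraries and is not a p-value. Of 532 list entries, 506 matched by symbol and 16 through RefSeq synonyms, and 10 were not matched.

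The 29 lists, the size rule, the placing of lists among random lists and the rule for named genes were fixed before the data were examined; gene groups and tests of explanations chosen later stand in the closing section and are named there. Named were Gata6-AS and Gata6, the listed neighbours of Gata6, and the 15 genes with the most positive and the 15 with the most negative differences past the size rule, without Rik, Gm, LOC and BC gene models and replication-dependent histones. Also named were, in each list standing apart, the 4 members with the most extreme difference in its direction, in other lists up to 4 members past the size rule, and the 6 genes per direction with the smallest p in the authors' deposited table. Actb, Gapdh, Gata4, Sox17, Foxa2, Xist, Pou5f1 and Nanog were named whatever they showed. Chosen after their values were seen were Cdkn1a, Col4a1, Col4a2, Dab2, Ddit3, Ddit4, Dnajb9, Dnajc3, Foxq1, Herpud1, Hspa5, Hspg2, Hyou1, Klf4, Klf5, Krt8, Krt18, Lama5, Nid2, Sdf2l1, Slc7a11, Vegfa, Vim, Xbp1, Eef1a1 and Sqle in the report. A few genes that this rule names are not reported here.

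Alternatives were a pseudocount of 0.1 or 0.5 RPKM, the median difference of expressed genes set to 0, each library scaled to 1000000 summed RPKM, no filter or a mean of at least 5 RPKM, a 1.5-fold size rule, all features kept, the mean in place of the median of a list, random lists not matched on expression, and limits of 0.05 and 0.01 on p in the authors' deposited table. Quantile normalization of both libraries, and a correction of the log2 difference for GC content and length of the longest GENCODE M21 transcript (medians in 10 bins of each), were added after seeing the data. A GC content and length were found for 97.7% of the genes tested.

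The scripts were tested on simulated data for this comparison, with counting noise as the only noise, on 10779 genes. The size rule called 0 of 49 genes changed 1.5-fold, 74.0% of those changed 2.5-fold, 98.0% of those changed 4-fold and 100% of those changed 8-fold. It called 0 of 10581 unchanged genes. Of 200 random lists without change, 5.50% stood apart, and 20 of 20 lists of 15 genes shifted by 0.30 were found. The least number of reads was at or below the simulated number in 300 of 300 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.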

Results

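Extraembryonic endoderm stem (XEN) cells are stem cell lines that stand for the primitive endoderm of the mouse blastocyst, the layer that gives rise to the visceral and parietal endoderm of the yolk sac. RNA of the female line PS10, of ICR strain, was sequenced after transfection of a locked nucleic acid (LNA) oligonucleotide against Gata6-AS, a noncoding RNA transcribed from the opposite strand beside the endoderm transcription factor gene Gata6, or of a control LNA. The comparison asks what the transcriptome of XEN cells looked like once this antisense RNA was targeted. There was 1 library per group, so differences have no replicate check, carry no p-value, and compare these 2 libraries rather than the conditions. For 790 genes in the control and 839 in the depleted library, RPKM multiplied by length was a whole number of equal steps. The step size corresponds to 1.04e+08 reads in the control library and 1.23e+08 in the depleted library. At the control depth, 1 RPKM over a kilobase of transcript is 104 reads, for which the exact 95% Poisson interval runs from 85.0 to 126 reads. A value of 0 over the same length allows up to 0.0290 RPKM in the control library and 0.0244 RPKM in the depleted library. The highest value in both libraries belonged to Eef1a1, at 3938 RPKM in the control and 3771 RPKM in the depleted library.

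The targeted RNA and Gata6 were both lower in the depleted library. Gata6-AS, carried in the table under the symbol 1010001N08Rik, stood at 10.1 RPKM in the control and 5.83 RPKM in the depleted library, a log2 difference of -0.70. Its level was 57.8% of control, with an exact (Clopper-Pearson) 95% interval of 50.5% to 66.1% from at least 369 and 538 reads. Gata6, a zinc finger factor that specifies primitive endoderm, stood at 81.9 RPKM in the control and 55.7 RPKM in the depleted library, a log2 difference of -0.55. That is 68.0% of control (66.8% to 69.3%, from at least 21891 and 27105 reads). These intervals cover counting error only and not the variation between cultures. In the mm9 assembly the antisense gene lies on the minus strand of chromosome 18 from 11049085 to 11052565, and Gata6 on the plus strand from 11052508 to 11085633, so that their ends share 58 bp in the annotation. Whether counting used the strand is not given in the sources used here, and reads in the shared stretch cannot be assigned to either gene. The values of the antisense gene may thus include reads of Gata6, so its 57.8% of control may not measure the depletion alone. In the authors' deposited table the log2 differences were -0.89 for the antisense gene (p = 0.0130) and -0.47 for Gata6 (p = 0.0746).

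**Figure D1:**
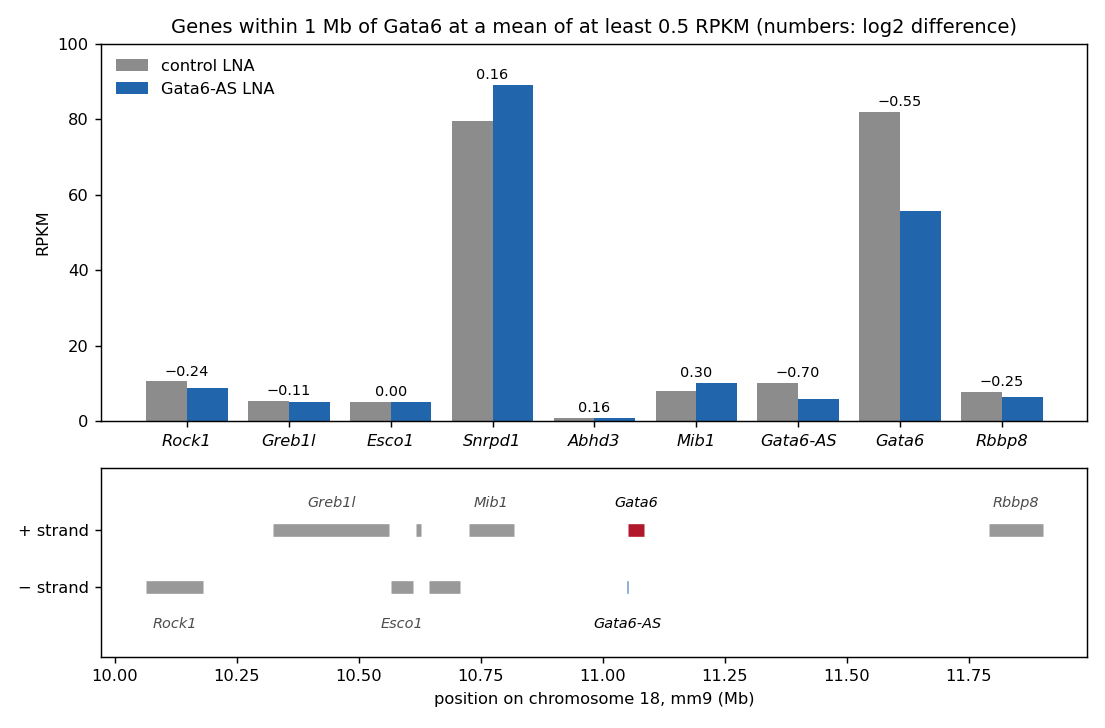
Upper panel: RPKM (linear axis from 0) of the genes within 1 Mb of Gata6 with a mean of at least 0.5 RPKM in the control library (grey) and the Gata6-AS depleted library (blue), 1 library each, with the log2(RPKM + 1) difference above each pair of bars. Lower panel: their positions by strand on chromosome 18 of mm9; Gata6-AS and Gata6 have the most negative differences, -0.70 and -0.55.

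Other genes around Gata6 on chromosome 18 differed less on the log2(RPKM + 1) scale. The 11 measured neighbours had a median log2 difference of -0.11, at percentile 4.60 among 10000 random lists of the same size and expression. None of them passed the 2-fold size rule. Gata6-AS and Gata6 did not pass it either, and lay at percentiles 1.23 and 2.30 of the differences of all genes tested. The nearest expressed genes on either side were Mib1, a ubiquitin ligase of Notch signalling, at 126% of control (8.02 RPKM in the control), and Rbbp8, a DNA end resection factor, at 81.9% of control (7.77 RPKM in the control). Osbpl1a had the lowest level relative to control among the neighbours above 1 RPKM, at 71.7% (5.09 RPKM in the control, log2 difference -0.39), followed by Riok3 at 80.4%, Npc1 at 81.8%, Rbbp8 and then Rock1 at 83.2%. In the authors' deposited table, however, the log2 difference of Osbpl1a was -0.53 (p = 0.0575), more negative than that of Gata6 there (-0.47). Greb1l stood at 91.7%, 6030446N20Rik at 98.8%, Esco1 at 99.9%, Impact at 108% and Snrpd1 at 112% of control. Abhd3, Cables1, Ttc39c, Lama3 and Zfp521 were below 1 RPKM in both libraries.

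Among 10868 genes with a mean of at least 1 RPKM, 36 were at least 2-fold higher and 49 at least 2-fold lower in the depleted library on the log2(RPKM + 1) scale, which understates the change of low genes. Of all these genes, 584 differed by at least 1.5-fold either way and 10284 by less. Their median difference was 0.05 and 58.0% of them lay above 0, so counts of list members above or below 0 stand against that share. With gene models known only by a number or clone name left aside, the genes with the most negative differences included Nupr1, a stress-induced chromatin protein, at 1.07 against 10.7 RPKM (log2 difference -2.49), and Bmper, a secreted regulator of bone morphogenetic protein (BMP) signalling, at 9.30 against 51.2 RPKM (-2.34). They were followed by the fatty acyl-CoA synthetase Acsl5 (-2.02), Dpcr1 (-2.00), the secreted protease Adamts9 (-1.86) and the amino acid transporter Slc1a4 (-1.75). Arrdc4 (-1.56), the amino acid transporter Slc7a5 (-1.55), the transcription factor Atf5 (-1.53), the ligand Bmp2 (-1.49) and Slco2b1 (-1.48) came next. The activin-binding protein Fst (-1.43), the pseudokinase Trib3 (-1.39) and the kinase Ptk6 (-1.39) were also among the 15 with the most negative differences. For Nupr1, the depleted library held 10.04% of the control level (8.92% to 11.3%), and for Bmper 18.2% (17.6% to 18.8%).

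With such gene models again left aside, the genes with the most positive differences included the carbonic anhydrase Car4, at 6.22 against 1.31 RPKM (log2 difference 1.64), and the BMP-responsive inhibitor of differentiation Id3, at 9.12 against 2.66 RPKM (1.47). Farnesyl diphosphate synthase, Fdps, stood at 36.7 against 12.7 RPKM (1.46). The Wnt antagonist Dkk1 (1.42), the glucose transporter Slc2a1 (1.37), Gadd45b (1.29), Ankrd1 (1.29), the microtubule minus-end protein Camsap3 (1.28) and the ligand Wnt7b (1.24) followed. Next were Sept4 (1.20), Tmem180 (1.20), the glycolytic enzyme Eno1 (1.18), the X-linked homeobox gene Esx1 (1.17) and the folate enzyme Mthfd1 (1.16). Of the 85 genes past the size rule, 20 overlap an expressed gene on the opposite strand, among them Adamts9 and Slc2a1. With a pseudocount of 0.1 the counts were 92 higher and 81 lower, with higher genes the more numerous.

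**Figure D2:**
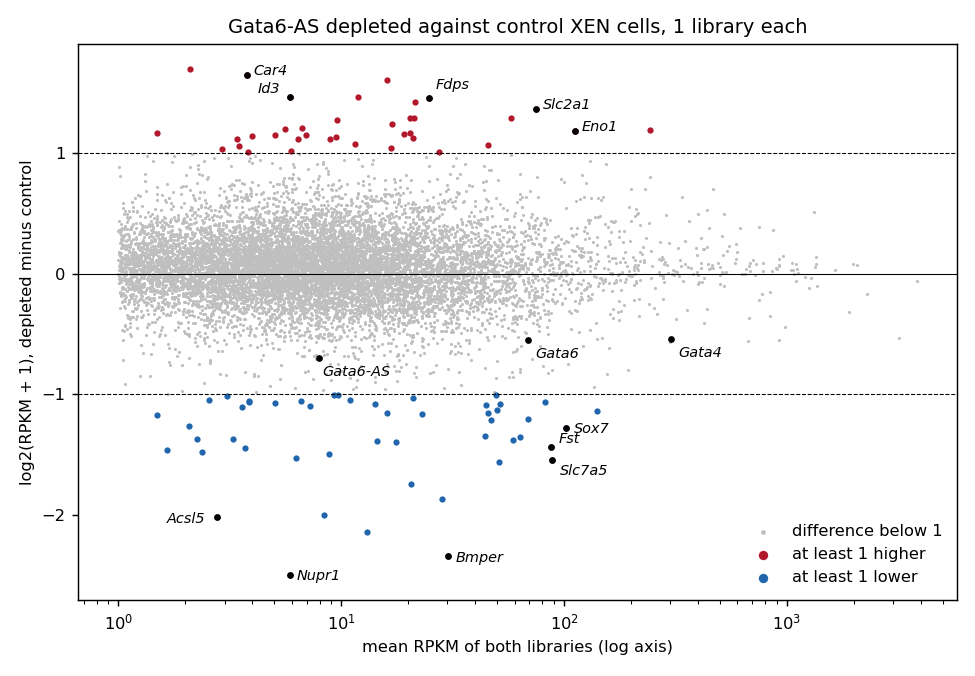
Difference of log2(RPKM + 1), depleted minus control (vertical axis), against the mean RPKM of both libraries (horizontal log axis) for 10868 genes. Red and blue points are the 36 genes at least 1 higher and the 49 at least 1 lower (dashed lines); black points are the genes labelled by name, from Nupr1 at -2.49 to Car4 at 1.64.

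Parietal endoderm genes were lower in the depleted library. Basement membrane genes and core regulators of XEN cells had medians below 0, with members on both sides. In the list of primitive endoderm and XEN core regulators, 1 of 15 measured members, Sox7, was at least 2-fold lower (59.4 against 145 RPKM, log2 difference -1.28) and none was 2-fold higher. Gata4 stood at 246 against 357 RPKM (-0.54), or 68.8% of control, Sox17 at 52.3 against 70.3 RPKM (-0.42), and Foxa2 at 35.9 against 35.1 RPKM (0.03). The transcription factor Foxq1 was at 43.6 against 22.0 RPKM (0.96), the endocytic adaptor Dab2 at 0.48, and the keratins Krt18 and Krt8 at 0.38 and 0.35. The list's median was -0.18 (percentile 0.60), with 8 members below 0 and 7 above; by the mean of its members it did not stand apart (percentile 8.06), nor after a correction for GC content and length chosen after seeing the data (11.4). Parietal endoderm genes had a lower median, -0.44 (percentile 0.00), with 13 of 15 members below 0 and 4 at least 2-fold lower: Fst (46.9 against 128 RPKM), the transcription factor Snai1 (35.3 against 91.8 RPKM), thrombomodulin, Thbd (13.8 against 32.2 RPKM), and the BMP antagonist Nog (32.6 against 66.7 RPKM). Basement membrane genes had a median of -0.23 (percentile 0.05), 12 of 17 below 0 and none past the size rule. The laminin genes Lamc1 (747 against 1094 RPKM, -0.55), Lama1 (-0.44) and Lamb1 (-0.35) and the nidogen gene Nid1 (-0.62) had the most negative differences there, while Nid2 was at 575 against 505 RPKM (0.19), Lama5 at 0.15 and the perlecan gene Hspg2 at 0.14. The collagen IV genes Col4a1 and Col4a2 belong to both lists but were below 1 RPKM in both libraries and do not count in either. Whether their low values come from the counting of reads was not tested. The parietal and basement membrane lists share 4 measured genes and are not independent.

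Visceral endoderm genes had a median of -0.12 (percentile 1.94), with 8 of 12 members below 0 and 4 above. Bmp2, at 4.13 against 13.4 RPKM, and Dkk1, at 31.5 against 11.1 RPKM, were the members past the size rule, in opposite directions. Beside Bmp2, the most negative differences were those of the secreted carriers Rbp4 (-0.30) and Trf (-0.22) and the endocytic receptor Cubn (-0.18). This list did not stand apart by the mean of its members (percentile 26.8), above a mean of 5 RPKM (2.89) or after the GC content and length correction (4.49). Endocytosis and lysosome genes, whose products take up and digest maternal proteins in the yolk sac, had 16 of 18 members below 0 and a median of -0.21 (percentile 0.11), with no member past the size rule. Lamp2 (-0.60), Ctsb (-0.33) and Lamp1 (-0.29) were among those with the most negative differences in it. Epithelial to mesenchymal markers had a median of -0.45 over 7 members (percentile 0.01), from Snai1 (-1.35), Mmp2 (-0.65), Itga5 (-0.60) and Zeb1 (-0.45), while the intermediate filament gene Vim was on the other side of 0 (0.64). Snai1 and Vim are also members of the parietal endoderm list. Epithelial junction genes were higher, with a median of 0.35 over 11 members (percentile 99.87) and the tight junction genes Cldn6 (8.30 against 3.59 RPKM, 1.02), Cgn (0.74) and Ocln (0.40) among those in front. FGF and MAP kinase targets had a median of -0.24 (percentile 0.04), with 9 of 13 members below 0 and 4 above. The feedback inhibitors Spry2 (-0.75) and Spry4 (-0.60) had the most negative differences, then Phlda1 (-0.30) and Dusp5 (-0.25). The call of this last list was lost above a mean of 5 RPKM (percentile 37.4).

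Cholesterol synthesis genes had the most positive median log2 difference of the lists, 0.77 (percentile 100), with 17 of 18 members above 0 and 5 at least 2-fold higher, among them Fdps, Idi1 (5.02 against 1.78 RPKM) and Sqle (5.45 against 2.20 RPKM). Glycolysis and hypoxia genes had a median of 0.18 (percentile 98.15), with Slc2a1 (108 against 41.3 RPKM) and Eno1 (155 against 67.9 RPKM) past the size rule and Slc2a3 (0.80) and Pfkl (0.73) next, but the hypoxia target Vegfa was at -0.81. This call was lost after the GC content and length correction (percentile 91.5), with quantile normalization, also chosen after seeing the data (95.8), and with random lists not matched on expression (97.2). The 17 measured p53 targets had a median of 0.44 (percentile 100), with 15 above 0 and none past the size rule. Trp53inp1 (0.76), Bbc3 (0.64), Zmat3 (0.56) and Ccng1 (0.55) had the most positive differences, and the cell cycle inhibitor Cdkn1a was at 0.44. ATF4 and endoplasmic reticulum stress genes had a median of -0.26 (percentile 0.00), 15 of 21 members below 0 and 6 above, and 4 at least 2-fold lower. These were Slc7a5 (44.7 against 133 RPKM), Trib3 (9.28 against 26.0 RPKM), asparagine synthetase, Asns (41.5 against 96.8 RPKM), and the lipoprotein receptor Vldlr (6.12 against 13.3 RPKM). Genes of the endoplasmic reticulum in the same list went both ways. The chaperone Hspa5 was at 411 against 264 RPKM (0.64), Sdf2l1 at 59.9 against 32.6 RPKM (0.86) and Hyou1 at 0.42. The co-chaperones Dnajb9 and Dnajc3 were at -0.47 and -0.21, the stress transcription factor Xbp1 at -0.60 and Herpud1 at -0.48. The other members above 0 were Ddit3 at 26.0 against 18.4 RPKM (0.48), the cystine transporter Slc7a11 (0.44) and Ddit4 (0.10).

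**Figure D3:**
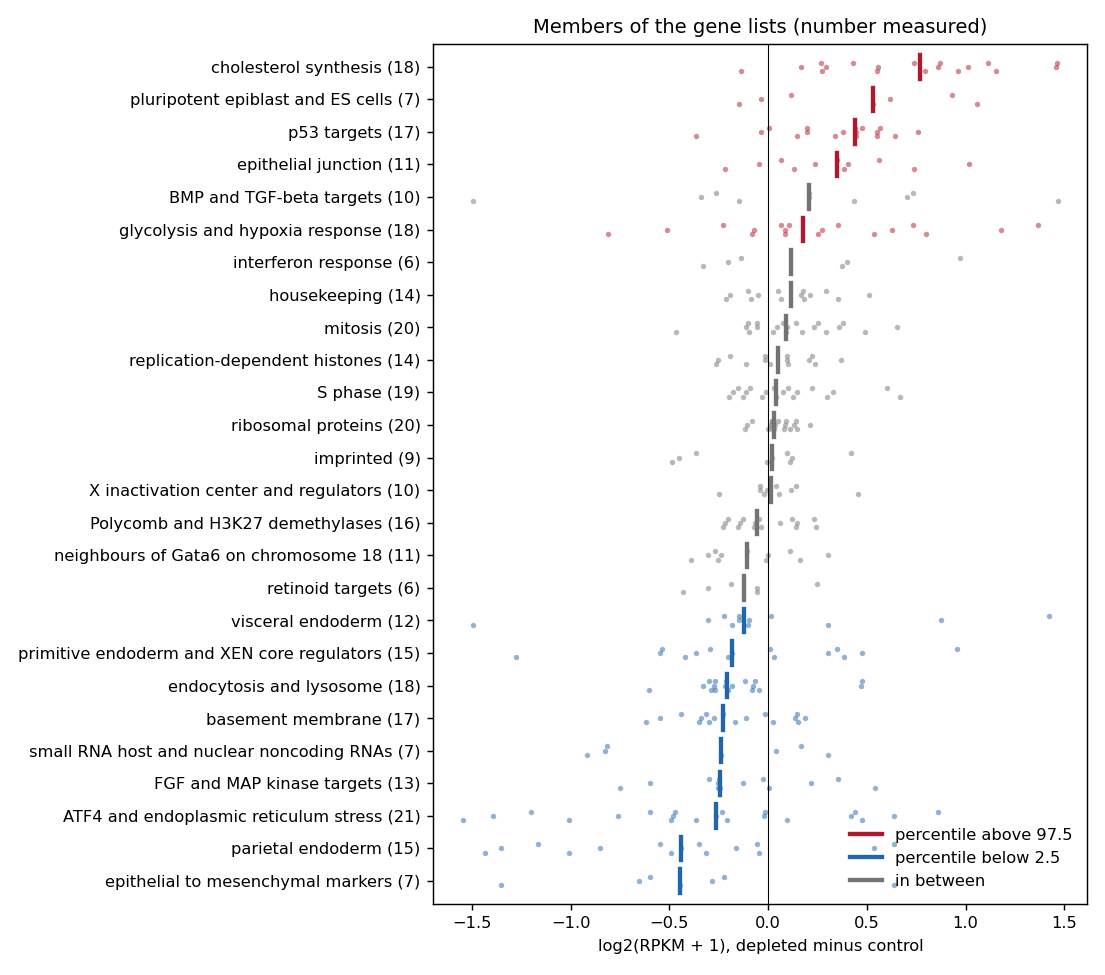
Log2(RPKM + 1) difference, depleted minus control (horizontal axis), of each measured member (points) of the 26 tested lists, with the list's median as a vertical bar and the number of members in brackets. Red and blue lists lie in the top or bottom 2.5% of random lists matched on expression; cholesterol synthesis has the most positive median (0.77) and epithelial to mesenchymal markers the most negative (-0.45).

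In the list of pluripotent epiblast and embryonic stem (ES) cell genes, 7 members were measured, with a median of 0.53 (percentile 100), 5 above 0 and 2 below. The RNA-binding protein gene Lin28a stood at 173 against 90.0 RPKM (0.93), Utf1 at 5.05 against 1.90 RPKM (1.06), Tcfcp2l1 at 13.6 against 8.54 RPKM (0.62) and Tbx3 at 9.45 against 6.22 RPKM (0.53). The core pluripotency gene Pou5f1 was near the limit of detection in both libraries, at 0.0541 and 0.0556 RPKM, and Nanog was at 5.07 against 4.61 RPKM (0.11). The members below 0 were Klf4 (53.4 against 59.2 RPKM, -0.15) and Klf5 (-0.03). Markers of trophoblast, fibroblast feeder cells and mesendoderm had 3, 4 and 1 members at a mean of 1 RPKM, fewer than the 5 needed to place a list. The small RNA host and nuclear noncoding RNAs, a list watched for library quality, had a median of -0.24 over 7 members (percentile 1.52, and 3.71 after the GC content and length correction). Snhg5 (-0.92), Neat1 (-0.83), Snhg1 (-0.81) and Gas5 (-0.24) had the most negative differences in it, while Xist, which silences an X chromosome in female cells, was at 59.8 against 58.2 RPKM (0.04).

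The remaining lists did not stand apart. BMP and TGF-beta targets had a median of 0.21 (percentile 95.80), with Id3 and Bmp2 past the size rule in opposite directions. Interferon response genes, which report on sensing of transfected nucleic acid, were at percentile 72.3 over 6 measured members, 3 above 0 and 3 below. The other members lay under a mean of 1 RPKM, so this list is a weak check on such sensing. S phase genes were at percentile 53.2, mitosis genes at 83.2, retinoid targets at 7.42, Polycomb and H3K27 demethylase genes at 8.66, imprinted genes at 40.9 and X inactivation genes at 37.0. Among the quality lists, replication-dependent histones were at percentile 48.2, ribosomal proteins at 49.2 and housekeeping genes at 87.5. Actb was at 455 against 371 RPKM (0.29) and Gapdh at 633 against 560 RPKM (0.18). In all, 5 lists stood apart as higher and 9 as lower out of 26, where chance alone gives 5% of lists, or 1.30. Without a filter on low values, 6 of these 14 lists no longer stood apart: XEN core regulators (percentile 10.3), pluripotency (80.005), glycolysis and hypoxia (90.2), FGF and MAP kinase targets (2.53), epithelial junction (91.9) and small RNA hosts (5.06). Some lists share members: XEN core regulators share Cubn, Dab2 and Lrp2 with endocytosis and lysosome, Krt8 and Krt18 with epithelial junction, and Cubn and Hnf4a with visceral endoderm. Cubn is also shared by visceral endoderm and endocytosis, P4ha1 by basement membrane and glycolysis, and Sesn2 by p53 and ATF4. Genes of a list are regulated together, so a list can also stand apart between any pair of cultures of the same cells.

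In the authors' deposited table, 2099 genes were listed, 1081 higher and 1018 lower in the depleted library, with p up to 0.07499. Their p-values come from 1 library per group; the test, and whether p was adjusted, are not given in the sources used here. All 85 genes past the 2-fold rule were listed in the authors' deposited table with the same direction. Both comparisons use the same 2 libraries, and all 2099 listed genes had the sign of their RPKM difference, so this is no independent check. Of the genes in the authors' deposited table, 801 had a mean under 1 RPKM and fell outside the 2-fold count, and 41 were listed at 0 RPKM in one of the libraries. The smallest p among lower genes in the authors' deposited table belonged to Nupr1 (1.67e-16), A730049H05Rik (9.19e-14), Acsl5 (7.48e-13), Bmper (1.55e-12), Dpcr1 (2.76e-10) and Slc1a4 (4.44e-09). Among higher genes in the authors' deposited table the smallest included those of Gm14136 (1.30e-06), Camsap3 (3.75e-06), Car4 (5.25e-06), Fdps (1.15e-05) and Mthfd1 (1.44e-05). A730049H05Rik lies within Adamts9 on the opposite strand of chromosome 6 and stood at 4.19 against 21.9 RPKM, beside 11.7 against 45.1 RPKM for Adamts9. Where exons of this pair overlap, reads cannot be told apart without strand. Exon positions were not examined.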

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

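The quantile normalization and the GC content and length correction were chosen after seeing the data. Gata6-AS and Gata6 were lower in the depleted library under every alternative, with Gata6 at -0.60 with the median set to 0, at -0.58 with summed RPKM equalized and at -0.59 after the GC and length correction. Such alternatives move differences little, so the direction of these genes was hardly at risk. The counts of genes at least 2-fold higher and lower depended on the pseudocount, with 92 and 81 at 0.1 and 59 higher at 0.5 RPKM. They were 66 and 76 with each library scaled to 1000000 summed RPKM, where a pseudocount of 1 weighs less, and 372 and 212 at 1.5-fold. All 85 genes past the size rule were kept under each of these, which was all but given beforehand. A pseudocount of less weight widens differences, and 1.5-fold is a looser rule. With the median set to 0, 80 were kept, with quantile normalization 79 and with the GC and length correction 77. Above a mean of 5 RPKM 64 were kept, where the others only fell to the filter.

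Of the 14 lists standing apart, 7 kept their call under every alternative run: parietal endoderm, basement membrane, endocytosis and lysosome, epithelial to mesenchymal markers, ATF4 and endoplasmic reticulum stress, p53 targets and cholesterol synthesis. Without a filter on low values, only 3 lists stood apart as higher, since genes near 0 RPKM have differences near 0 on this scale. The trophoblast list, not testable otherwise, was then at percentile 99.0, with a median of only 0.04 over 15 members. Most of these members had a mean below 1 RPKM, so the percentile does not show trophoblast genes to be higher. After the GC and length correction, 4 calls were lost: XEN core regulators (percentile 11.4), visceral endoderm (4.49), glycolysis and hypoxia (91.5) and small RNA hosts (3.71). None of the 14 lists changed sides, and the 12 lists not standing apart stayed so. In the authors' deposited table, 223 higher and 251 lower genes had a p of at most 0.01. Of 42 named genes past the size rule, 42 kept their direction and 41 their size under 4 alternatives. Depth limits little here; the lack of a second culture per group does. No paired analysis was possible because each group has 1 library.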

Other observations

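The gene groups in the next paragraphs, the genes named from them, and the tests of endoplasmic reticulum load, of nutrient state, of the overlap with the antisense gene and of ES cells were chosen only after the result was seen; the other tests were fixed before theirs. Cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, were lower in the depleted library. Of 19 (Wars, whose lower value had been seen, left aside), 15 were below 0, with a median log2 difference of -0.49 (percentile 0.00), and Lars (34.9 against 64.5 RPKM), Gars (40.0 against 73.3 RPKM) and Nars (61.0 against 109 RPKM) had the most negative ones. The 17 mitochondrial synthetases had a median of 0.18 (percentile 95.9). Single enzymes of serine and folate metabolism, not tested as a list, lay on both sides: Mthfd2 at -1.38, Psph at -1.13, Shmt2 at -1.08 and Psat1 at -0.76, but Phgdh at -0.02 and Mthfd1 at 1.16. Among genes of amino acid transporters, Slc7a1 was at -1.09, Slc6a9 at -0.83, Slc3a2 at -0.54 and Slc38a2 at -0.24, but Slc7a11 at 0.44. Atf4 itself was at 136 against 138 RPKM. In the opposite direction stood 13 chaperones of the endoplasmic reticulum (median 0.38, percentile 99.97, with 12 above 0), of which 4 are also in the ATF4 and endoplasmic reticulum stress list, 12 genes of fatty acid synthesis (median 0.41, percentile 100, all above 0) and 15 of ribosome biogenesis (median 0.30, percentile 99.9, with 13 above 0, but Nop58 at -0.45).

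Among genes of secreted BMP and activin binding proteins, not tested as a list, Bmper, Fst and Nog stood at 18.2%, 36.5% and 48.9% of control, and Chrd, near 1 RPKM, at 84.2%. The BMP-responsive genes Id1 and Id3 were at 196% and 343% of control, and Bmp2 itself was at 30.7%, while Smad7 was at 75.4%. The Wnt feedback gene Axin2 was at 34.9% of control and the Wnt antagonist Dkk1 at 283%.

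Genes whose spans, introns included, lie inside another gene on the opposite strand had differences related to those of that gene. Whether their exons overlap was not examined. Among 375 pairs in which a gene lies inside another on the other strand, the Spearman correlation of their log2 differences across pairs was 0.63, and among the 230 of them whose inner gene is a Rik, Gm, LOC or BC gene model it was 0.83, against 0.13 for 4771 adjacent pairs on opposite strands without overlap; genes are not independent replicates. The model Gm12868 overlaps Slc2a1 and stood at 258% of control beside 262% for Slc2a1.

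The ATF4 and endoplasmic reticulum stress list was lower in the depleted library. A lower load on the endoplasmic reticulum, as the cause of the whole pattern, would put 9 chaperones outside the list below percentile 2.5. They lay at percentile 98.8, all above 0, which argues against it. This rule was set after the list had been seen, in which the chaperones Hspa5, Sdf2l1 and Hyou1 were already above 0. A lower load stays open for Xbp1, Herpud1 and Dnajb9 (median -0.48). These genes were picked because they were lower, so their median cannot decide it. The test of a GC content or length bias as the whole cause was weak. Its correction had an SD over genes of only 0.07, and the list stayed at percentile 0.00 after it. A lower amino acid branch of the ATF4 programme is a candidate explanation: the cytosolic synthetases, whose values had not been seen when the prediction was made, lay at percentile 0.00 and the mitochondrial ones did not, but Slc7a11 (0.44), Ddit3 (0.48) and Ddit4 (0.10) of the list were above 0. Whether this came from the LNA or from a different nutrient state of the cultures cannot be told apart with 1 culture per group.

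Gata6 was lower together with its antisense RNA. Reads of the antisense gene counted in Gata6 are argued against as the whole cause. Gata6 lost at least 2.38 times the reads that the whole antisense gene could at most have held in the control library (83.7 against 35.1 reads per 1000000). The trend with GC content and length was too small to account for the lower Gata6. Gata6 was at -0.55 before the correction and at -0.59 after it. Over genes the correction had a 5th percentile of -0.13 and a 95th percentile of 0.11. The rule set for such a bias could thus hardly have been met, and its outcome adds no support. A bias that the correction does not model was not tested. A loss of Gata6 through its antisense RNA may account for the pattern, as may a difference between the cultures, and nothing here separates them. Reads of Gata6 counted in the antisense gene were not tested, and they may account for part of the lower level of the antisense gene.

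The pluripotency list was higher in the depleted library. ES cells in that culture are argued against by Pou5f1, Sox2, Zfp42, Dppa5a and Fgf4, abundant in such cells, whose highest value there was 0.526 RPKM, while Lin28a alone was 82.5 RPKM above control. A low value does not always show a gene to be off here, since the housekeeping gene Gusb was at 0.107 RPKM in that library, so this rests on all 5 genes together. The trend with GC content and length, whose correction had an SD over genes of 0.07, was too small to account for the list's median of 0.53. After the correction the list was at percentile 100 (median 0.49), an outcome close to fixed beforehand. The list may reflect a few genes that XEN cells express themselves, such as Lin28a, which stood at 90.0 RPKM in the control library; this was not tested, and a difference between the cultures stays open.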
